A study of Hordeum vulgare with 4 samples.

How the data were processed

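RNA sequencing was done on leaves of barley (Hordeum vulgare) cultivar Golden Promise, per the labels, in 2 wild-type libraries and 2 libraries of plants that constitutively express HvHSFA2e, a heat-inducible barley heat shock transcription factor. Per the labels, libraries were made from DNase-treated total RNA with a SMARTER mRNA-Seq kit. The labels assign a heat stress of 30 minutes at 42 °C to all 4 libraries, while the treatment protocol in the same labels gives 40 °C for 4 hours and the extraction protocol mentions no heat and an older plant age. The heat exposure of the sequenced leaves is therefore uncertain, and with no unheated library the comparison is of genotypes only. The labels do not say whether the 2 libraries of a genotype came from separate plants, so p-values measure the spread between these libraries, which may be technical.

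The submitters' processing notes name STAR, Bowtie2, RSEM and DESeq2, without versions or roles. Feature names carry the prefix that Trinity, a transcript assembler, gives in its genome-guided mode, per the file headers. In this mode reads are first aligned to a genome and divided into partitions of overlapping reads, and the number after the prefix is that of the partition. The genome build and the assembler's settings are not given in the sources used here. The tables hold 92519 assembled isoforms of 63254 genes in 34245 partitions, of which 13870 hold 2 or more genes. A gene here is an assembled model, and 1 locus may be split over several models.

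The unit of each table was checked from its values. The isoform count table holds the authors' RSEM expected counts, which estimate the reads of each isoform and need not be whole. The 2 expression tables hold a signal that the authors made as TPM scaled with 1 TMM factor per library, per the file names: the geometric mean of the 4 library sums, divided by the sum of an unscaled TPM column, is 0.999999 in both tables. The deposited gene count table does not hold reads per gene. It is also a normalized signal, proportional to TPM within each library: over 16260 genes with a value above 20 in it and above 1 in the expression table, the SD of the log2 ratio to the gene expression signal was at most 9.81e-05. Its library sums equal the read totals, but 96.5% of genes with reads have a value there that differs by more than 10% from the summed expected counts of their isoforms in at least 1 library. The design, fixed before the data were examined, had named that table as read counts. The test the unit needs was run in its place on the isoform expected counts summed per gene, and the deposited gene table became an alternative.

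Summed expected counts were rounded to whole numbers and genes were kept with edgeR 4.0.16 filterByExpr at its defaults (minimum count 10, minimum total 15), which left 25095 genes. Counts were scaled with TMM and tested with edgeR's quasi-likelihood test (R 4.3.3) with genotype as the only factor and Benjamini-Hochberg adjustment, and genes were called at an adjusted p under 0.05. Isoforms were tested in the same way. Isoform usage within genes was tested with edgeR's diffSpliceDGE on genes with at least 2 kept isoforms. Standard errors of log2 fold changes were taken as the fold change divided by the square root of its F statistic. CPM values were computed on TMM-scaled library sizes, except that the limit of 1 CPM for genes read in a single genotype used unscaled library totals. With 2 libraries per genotype an exact two-sided permutation test of a single value cannot go below p = 0.333, so single values are given with their SD and without a test. For a genotype without reads of a gene, that is, with expected counts that round to 0 in both of its libraries, a floor of 3 reads over both libraries was used, and intervals and floors cover counting error only.

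Library totals of expected counts were 6030406 and 22631196 in the wild type and 14488461 and 14128916 in the overexpression plants, so the shallower wild-type library limits the precision of low genes. On simulated data for the gene-level comparison (24310 genes kept, 200 changed, dispersions on the fitted trend), the fit recovered 29.9% of 2-fold, 82.1% of 4-fold and 93.9% of 8-fold changes with 3.52% of calls false. With each gene's own estimated dispersion, 22.3% of calls were false in that simulation, from 40 false calls among 24354 genes. For isoforms on the trend (35158 kept), 7.46%, 50.7% and 68.2% of 2-fold, 4-fold and 8-fold changes were recovered with 5.62% of calls false. With own dispersions (35234 kept) these were 0%, 32.8% and 56.1%, with 18.1% of calls false. For isoform usage (6098 genes), 9.09% of 4-fold and 42.4% of 8-fold changes of 1 isoform were recovered with 0 false calls on the trend. With own dispersions 15.6% of 8-fold changes were recovered and 70.6% of the calls were false. In each simulation the 200 changed genes or isoforms were drawn from those with an expected count of at least 10 in the smallest library. Recovery of lower ones was therefore not measured. The data gave 8715 gene calls. Recovered and false shares depend on how many genes changed, so these shares do not carry over to the real fit.

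No name is paired with the identifiers in the files used here, and 0 of 63254 gene identifiers occur in the barley gene table that was at hand. HvHSFA2e itself and the lists of heat shock, hormone, stress and secondary metabolism genes fixed in advance were therefore not analysed here. The rule for named genes, fixed in advance for this case, takes the 2 identifiers that rose and the 2 that fell with the smallest adjusted p among those with an average log2 CPM of at least 2, an absolute log2 fold change of at least 1 and both libraries of one genotype above both of the other. Fold classes, level classes and genes read in a single genotype were chosen as groupings after the data were seen.

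Alternatives were RLE, upper quartile and library-size scaling, DESeq2 1.42.0, limma 3.58.1 (voom, and its trend method on log2 expression plus 1 or 0.1), no filter or a filter of 50 counts in 2 libraries, thinning to the smallest library, a replicate block, leaving out the 20 most abundant features, and leaving out each library in turn. The deposited gene table and sums per partition were added after seeing the data. The replicate numbers are shared by the genotypes, but the labels do not say that they pair plants.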

Results

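Leaf transcriptomes of barley plants that constitutively express the heat shock factor HvHSFA2e were compared with those of the non-transformed cultivar Golden Promise, a line widely used for barley transformation. The study asks what this heat-inducible regulator does in abiotic stress responses and development, with heat and drought tolerance, phytohormones and secondary metabolism named in its title. Expected read counts of assembled isoforms, summed per gene, were available for 2 wild-type and 2 overexpression libraries. The totals were 6030406 (replicate 1) and 22631196 (replicate 2) reads in the wild type, and 14488461 and 14128916 in the overexpression plants. Genes carry assembly identifiers without names or coordinates in the files used here, so results are given for groups of genes and for 4 identifiers.

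The libraries separated by genotype. The first principal component of log2 CPM over 25095 genes held 82.0% of the variance, with the wild-type libraries at -121.6 and -108.5 and the overexpression libraries at 115.7 and 114.3. Across genes, which are not independent replicates, Pearson's r of log2 CPM was 0.961 between the wild-type libraries and 0.962 between the overexpression libraries, against 0.804 to 0.826 between genotypes. Spearman's rho was 0.968 and 0.966 within genotypes and 0.832 to 0.851 between them. No library was a copy of another: chi-square per degree of freedom of the counts was 8.16 between the wild-type libraries and 17.8 between the overexpression libraries.

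Of the 25095 genes tested, 8715 (34.7%) differed between the genotypes. In the overexpression plants 4670 genes were higher and 4045 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The median log2 fold change was 1.85 among the higher genes and -1.19 among the lower ones, and 3822 of the higher and 2492 of the lower genes differed at least 2-fold. In all 8715 called genes both libraries of one genotype lay above both of the other, as did 72.0% of all tested genes (chance gives 33.3%). Both wild-type libraries mattered for the number of calls: without replicate 1 there were 2505 higher and 2359 lower genes, and without replicate 2 there were 1500 and 1498. Scaling to library size alone moved the median log2 fold change of all genes from 0.06 to 0.32 and the share of higher genes among the calls from 53.6% to 71.1%.

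**Figure D1:**
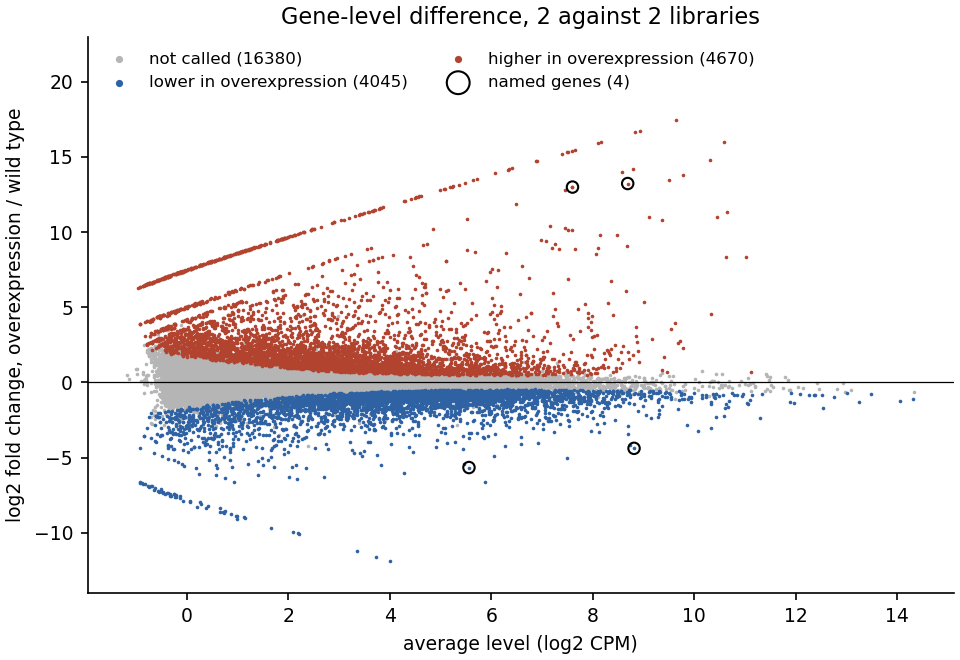
Log2 fold change of overexpression over wild type (y axis) against the average level in log2 CPM (x axis) for the 25095 genes tested, 1 point per gene, with the 4670 genes called higher, the 4045 called lower and the 4 named genes marked. Points far above 0 outnumber points far below it; straight rows of points at the edges are genes with few or no reads in one genotype, whose fitted fold depends on the prior count.

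Both named genes that rose went from 2 reads or fewer per wild-type library to means of 387 CPM and 824 CPM. TRINITY_GG_24419_c0_g1, assembled as 11 isoforms, had 0 and 2 reads in the wild-type libraries and 824 ± 112 CPM (SD, n = 2) in the overexpression libraries. Its ratio of pooled reads, each divided by the genotype's TMM-scaled library sizes, was 10597. The exact 95% counting interval was 2933 to 87504 (edgeR adjusted p = 3.49e-05). TRINITY_GG_9319_c0_g1, a model with 1 isoform, had 0 and 1 reads in the wild type and 387 ± 70.1 CPM (SD, n = 2) in the overexpression plants. Its ratio, scaled in the same way, was 9932 with an interval of 1782 to 392344 (edgeR adjusted p = 3.49e-05).

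The named genes that fell kept a measurable level. TRINITY_GG_24375_c0_g1 fell from 93.3 ± 6.01 CPM in the wild type to 1.83 ± 0.0790 CPM in the overexpression plants (SD, n = 2 each), a log2 fold change of -5.66 ± 0.20 (SE, edgeR adjusted p = 3.49e-05). TRINITY_GG_5946_c0_g1, an abundant gene of the wild-type leaf, fell from 859 ± 77.2 to 41.1 ± 2.52 CPM (SD, n = 2 each), a log2 fold change of -4.39 ± 0.19 (SE, edgeR adjusted p = 6.33e-05).

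Large changes were mostly increases. At least 16-fold, 846 called genes were higher and 159 lower in the overexpression plants, and at least 64-fold the numbers were 472 and 67. Among the 7654 genes with a wild-type mean of at least 16 CPM, 7 were higher and 27 lower at 16-fold or more. That limit leaves out 220 of the 227 such increases that reach 16 CPM in the overexpression plants. Among the 7709 genes with an overexpression mean of at least 16 CPM, 227 were higher and 2 lower. Each limit favours a direction, so neither order shows how well-expressed genes moved. Folds were also taken as ratios of mean CPM for all tested genes, with genes unread in a genotype set to the floor of 3 reads. The numbers of called genes were then 738 and 139 at 16-fold and 233 and 18 at 64-fold. The effects of the fold measure and of the floor were not separated. The 846 genes took 0.0561% ± 0.0030 of the reads in the wild type and 6.88% ± 1.29 in the overexpression plants (SD, n = 2 each). The 159 genes took 0.372% ± 0.0120 of the reads in the wild type and 0.0188% ± 0.0005 in the overexpression plants. These shares describe genes chosen for their difference in the same libraries. Without wild-type replicate 2 the 16-fold numbers were 509 and 107, and without an overexpression library they were 836 and 332 (replicate 1 left out) or 974 and 339 (replicate 2 left out).

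**Figure D2:**
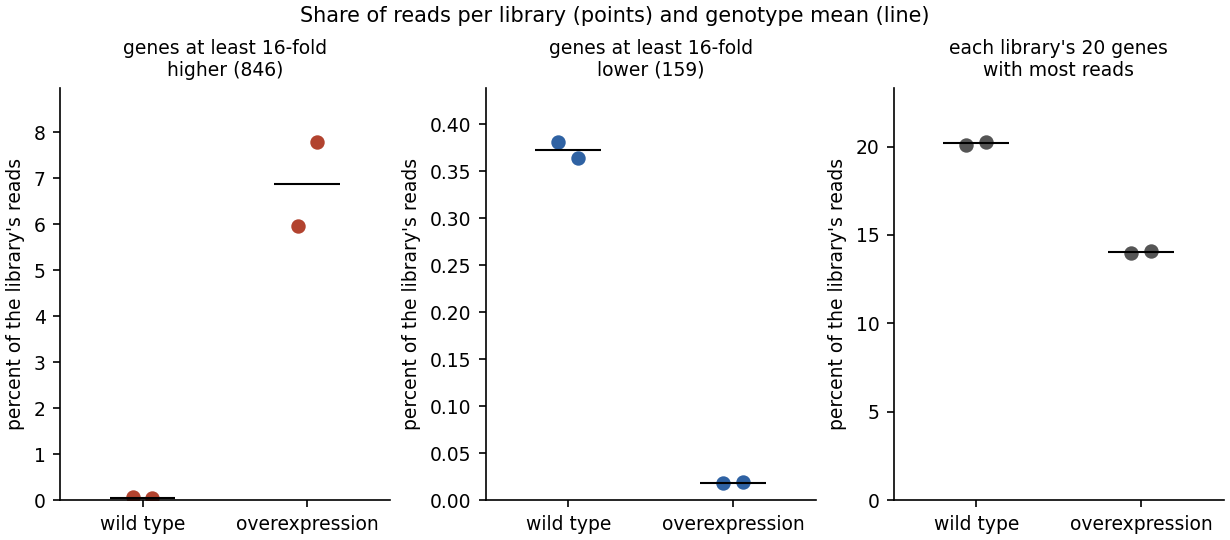
Percent of each library's reads (y axis) taken by the 846 genes at least 16-fold higher, by the 159 genes at least 16-fold lower and by each library's own 20 genes with most reads, for wild-type and overexpression libraries (points) with the mean of each genotype (lines). The higher genes lie at 5.96% and 7.79% in the overexpression libraries and under 0.06% in the wild type, and the 20 leading genes at 20.1% and 20.3% in the wild type and 14.0% and 14.1% in the overexpression plants.

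A group of genes was read in one genotype only, with each library's expected count of a gene rounded to a whole number. At 1 CPM or more in both overexpression libraries, 244 genes had no read among 28661602 wild-type reads, and all 244 were called higher. The converse group, unread among 28617376 overexpression reads, held 35 genes. Pairs of 1 wild-type and 1 overexpression library gave 8 to 14 such genes. Of the 244 genes, 59 averaged at least 10 CPM in the overexpression plants and 17 at least 100 CPM, while 3 of the 35 wild-type genes reached 10 CPM and 0 reached 100. The most abundant of the 244 had 1237 and 1956 CPM in the overexpression libraries, at least 13771-fold above the floor of 0.116 CPM that 3 reads over both wild-type libraries give. The 244 genes together took 0.954% and 1.16% of the reads in the overexpression libraries. Without wild-type replicate 2, the deepest library, the groups held 619 and 105 genes, and without overexpression replicate 2 they held 466 and 75. The smaller group also grew without wild-type replicate 1 (64 genes) and without overexpression replicate 1 (81 genes).

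The balance between higher and lower genes changed with expression level. Among the 496 genes averaging at least 256 CPM over the 4 libraries, 75 were higher and 189 lower in the overexpression plants, and between 64 and 256 CPM 300 were higher and 661 lower. From 1 to 4 CPM, 1388 genes were higher and 600 lower, and below 1 CPM 433 were higher and 154 lower. The median log2 fold change went from 0.65 below 1 CPM to -0.38 at 256 CPM or more. Under library-size scaling these medians were 0.90 and -0.13, with 107 higher and 133 lower genes at 256 CPM or more and 461 in each direction between 64 and 256 CPM. At 256 CPM or more, 56 genes were higher and 91 lower without wild-type replicate 1, and 55 in each direction without replicate 2. From 64 to 256 CPM the numbers without these libraries were 172 and 448, and 143 and 287. From 1 to 4 CPM they were 745 and 244, and 285 and 148, and without overexpression replicate 1 they were 891 and 566. The class below 1 CPM held 110 higher and 19 lower genes without wild-type replicate 1, 116 and 92 without overexpression replicate 1, and 140 and 98 without overexpression replicate 2. Without wild-type replicate 2 the excess of higher calls in that class was lost, while its median log2 fold change was 0.73.

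**Figure D3:**
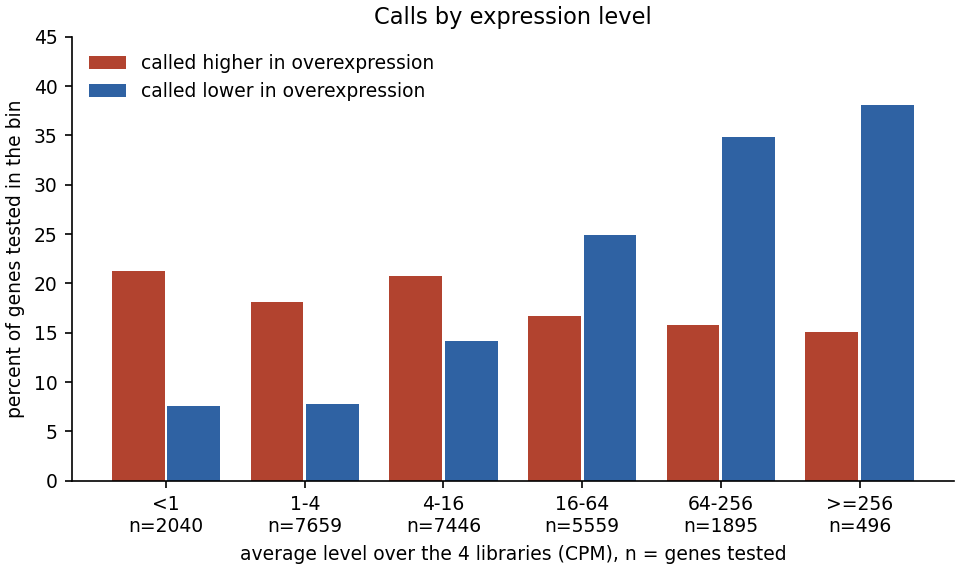
Percent of tested genes called higher or lower in the overexpression plants (y axis, bars from 0) in 6 classes of average CPM over the 4 libraries (x axis, with the number of genes per class). Lower genes rise from 7.55% of the genes below 1 CPM to 38.1% at 256 CPM or more, while higher genes go from 21.2% to 15.1%; under library-size scaling the class from 64 to 256 CPM holds as many higher as lower genes.

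The most abundant transcripts of the leaf took a smaller share of the reads in the overexpression plants. The 20 genes with the highest mean level took 20.1% ± 0.066 of the reads in the wild type and 13.8% ± 0.049 in the overexpression plants (SD, n = 2 each). Of these genes edgeR called 12 lower and 0 higher (0 higher also at an unadjusted p under 0.05 and by DESeq2), with a median log2 fold change of -0.77 (-0.51 under library-size scaling). In the edgeR test the 12 calls needed both wild-type libraries. Without replicate 1, 1 gene was called lower, and without replicate 2, 0 were (9 at an unadjusted p under 0.05, 11 by DESeq2), with medians of -0.77 and -0.81. Of the 100 genes with the highest mean level, 42 were lower and 7 higher. Without wild-type replicate 1 those were 14 and 6, and without replicate 2 they were 6 and 6. Without overexpression replicate 1 they were 52 and 14, and without overexpression replicate 2 they were 64 and 8.

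The overexpression libraries also held more detected genes at equal read totals, although fewer of their reads went to the 20 leading genes, which leaves more reads for the rest. With all libraries thinned to the smallest library (6030406 reads), 41938 and 40000 genes had at least 1 read, after rounding, in the overexpression libraries and 36518 and 36412 in the wild type. Unthinned, 49089 and 47018 genes were detected in the overexpression libraries and 36518 and 46805 in the wild-type libraries.

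In the edgeR test single isoforms gave fewer calls than whole genes. Of 38337 isoforms tested, 2686 were higher and 2137 lower in the overexpression plants (edgeR quasi-likelihood test, adjusted p under 0.05), and the common dispersion was 0.186, against 0.0455 for genes. The called isoforms belonged to 3985 genes, of which 3577 were also called as genes. This order depended on the method: limma on log2 expression plus 1 called 5294 isoforms higher and 3703 lower, against 4666 and 3759 genes. In 64 genes 1 isoform or more rose while another fell, and 34 of these were not called as whole genes. With a library left out the isoform counts were far lower: 553 higher and 195 lower without wild-type replicate 1, 162 and 51 without wild-type replicate 2, 1154 and 879 without overexpression replicate 1, and 1004 and 832 without overexpression replicate 2. RSEM divides reads among near-identical isoforms by estimate, and that division is uncertain.

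Isoform usage, the division of a gene's reads among its isoforms, was called different in 597 of 6849 genes with at least 2 tested isoforms (edgeR diffSpliceDGE, adjusted p under 0.05). Of these, 291 were also called at the gene level and 306 were not. The number rested on every library: it was 102 without wild-type replicate 1, 246 without wild-type replicate 2, 19 without overexpression replicate 1 and 14 without overexpression replicate 2. The isoform with most reads was another one in the 2 genotypes, and the same in both libraries of each, in 265 of the 6849 genes, of which 57 were among the 597 that passed the usage test. Crossed pairings of 1 wild-type with 1 overexpression library gave 64 and 70 such genes.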

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

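The direction of all 4 named genes and their side of the threshold held in all 68 combinations of gene and alternative, with adjusted p-values up to 0.0236. These 4 genes were picked for the smallest adjusted p in the same libraries, so they give no independent measure of stability. Their log2 fold changes ranged from 8.58 to 16.3 for TRINITY_GG_24419_c0_g1, 8.70 to 15.2 for TRINITY_GG_9319_c0_g1, -5.75 to -4.98 for TRINITY_GG_24375_c0_g1 and -4.51 to -4.13 for TRINITY_GG_5946_c0_g1. The number of higher genes stayed within 1.5 times its value in 15 of 18 alternatives and that of lower genes in 14 of 18. DESeq2 called 3501 higher and 3633 lower genes. Library-size scaling gave 2572 lower genes beside 6334 higher ones. The deposited gene table, added after seeing the data, gave 1531 higher and 1401 lower genes and 0 of the 20 most abundant genes as lower in edgeR (14 at an unadjusted p under 0.05). With a library left out, higher genes numbered 1500 to 4204, lower genes 1498 to 4293, genes at least 16-fold higher 509 to 974 and at least 16-fold lower 107 to 339, and lower genes among the 20 most abundant 0 to 18. Leaving a library out leaves 1 residual degree of freedom, and the lone library is assumed to vary like the other genotype's. Genes at least 16-fold higher and lower numbered 1563 and 400 without a filter, which adds genes with few reads, 421 and 41 under the filter of 50 counts, which removes them, and 252 and 30 with limma on log2 expression plus 1, whose pseudocount caps the fold of low genes. Thinning gave 96 lower genes at 16-fold. Limma called 6 (plus 1) and 7 (plus 0.1) of the 20 most abundant genes lower; the cause was not tested. Genes read in overexpression libraries only numbered 325 to 619 with a library left out and those read in wild-type libraries only 64 to 105, since fewer libraries had to be without reads or above the level. Higher and lower isoforms each moved by over 1.5 times in 7 of 16 alternatives, and isoform usage in 7 of 7. With a library left out, 162 to 1154 isoforms were higher and 51 to 879 lower, and isoform usage was called in 14 to 246 genes. DESeq2 called 3227 isoforms lower. Limma called 5294 isoforms higher and 3703 lower (plus 1) and 4374 higher (plus 0.1). Usage was called in 319 genes under the filter of 50 counts and in 373 without isoforms under 10% of their gene's reads, both of which test fewer isoforms. The deviations of same-numbered libraries correlated at 0.0024 across genes. Counting error in low genes weakens such a correlation, so it does not exclude a pairing. With a replicate block the gene-level numbers were 4555 higher and 4067 lower, isoforms 588 higher and 347 lower, and usage was called in 9 genes; the cause was not tested. The planned tests of HvHSFA2e and of the gene lists were not run, because the identifiers are not paired with names in the files used here. Wild-type replicate 1 holds 6030406 reads, which limits the precision of low genes, but the effect of depth by expression level was not tested.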

Other observations

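The tests of thinned libraries, of scalings and of room to fall by the level in the higher genotype were chosen after related results were seen, and the shuffle of directions within partitions had no prediction written in advance. Genes assembled from one partition of the reads mostly moved in one direction. In 766 partitions with at least 2 called genes, 94.3% had called genes of a single direction, against a median of 46.5% and at most 52.3% when directions were shuffled among called genes 1000 times. Summed per partition, 4072 partitions were higher and 3698 lower in the overexpression plants, so the number of gene-level calls may count some loci more than once. These sums do not remove repeats over different partitions. TRINITY_GG_10558_c0_g1 and TRINITY_GG_10559_c0_g1, of different partitions, were both called with identical values. Both had a log2 fold change of 1.11, with means of 5.08 CPM in the wild type and 10.6 CPM in the overexpression plants. How many models are so repeated was not counted. Whether called genes of one partition are pieces of 1 locus or separate neighbours was not tested.

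The first pattern is the group of 244 genes read in overexpression libraries and with counts that round to 0 in the wild type, against 35 the other way. Shallow wild-type libraries do not account for it: with all libraries thinned to one depth the groups held 307 and 50 genes, a ratio of 6.14. Splitting of loci within a partition does not account for the imbalance either: partitions gave 182 and 26, a ratio of 7. Loci split or repeated over several partitions were not tested. If wild-type reads had gone to another model of the same locus, that model should have been called lower. This held for 0% of the 244 genes, but only 71 of them share a partition with another tested gene. The check therefore covers only those 71 genes and models of the same partition. Of the 244, 187 (76.6%) lie in partitions without any wild-type read. Only 100 share a partition with another gene that has reads, and for the rest the lack of wild-type reads follows from their selection. What stays open and untested is the genotype itself, an unequal heat exposure or handling of the plants, and sequences present in a single plant stock. The identifiers carry no sequence or name, so RNA of another organism stays open too, as far as its reads aligned to the genome that guided the assembly.

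The second pattern is the excess of increases at 16-fold or more, 846 against 159 genes. Scaling may shift such a balance, but the ratio of higher to lower genes was 5.20 to 6.66 under the 4 scalings run. The median log2 fold change of all genes lay between 0.05 and 0.32 under these scalings. That range is small beside a 16-fold limit, so a larger difference in scaling was not tested. A lack of room to fall among low wild-type genes stays open, because the answer depends on where the level limit is set: among genes with a wild-type mean of at least 16 CPM the ratio was 0.259 (7 higher, 27 lower), and with the limit set in the higher genotype, or in either, it was 8.41 (227 higher, 27 lower). The first limit leaves out all increases that start below 16 CPM in the wild type, among them 220 of the 227 that reach 16 CPM in the overexpression plants, and the second admits low wild-type genes only if they rose. The genotype, the plants' treatment and any other difference that shares the same split of the libraries stay open too. Of the 3 splits of the 4 libraries into pairs, 1, the real one, called as many as 8715 genes, and the highest other called 0 in edgeR. The other splits gave 67 and 71 genes at an unadjusted edgeR p under 0.05, and 7 and 5 by DESeq2. Each of them puts 1 library of each genotype in each pair, so the genotype difference adds to the spread and lowers the calls. They therefore do not show how many calls arise without a genotype difference, and so few splits cannot give a share under 0.05.

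The third pattern concerns the processing. The deposited gene table, used as if it held reads, called 2932 genes in place of 8715, and 2477 were called by both, 0 of them in opposite directions. By scaled values, 12442 genes pass the low-count filter that do not pass it by reads. Their median was 7.60 reads over the 4 libraries but 68.4 in the table, and the common dispersion was 0.393, against 0.0455 for reads. Tested on the 25095 genes of the read-based fit alone, the scaled values called 7768 genes, and on the 13170 of these whose scaled value is at most their reads they called 5152, against 5321 from reads. These results are consistent with low-read models, scaled up by their short length, raising the shared estimate of spread for all genes. No biological explanation was tested for this pattern.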
